A study of Homo sapiens with 6 samples.

How the data were processed

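Gene expression was measured by RNA sequencing in 6 libraries of U251 cells, an established human glioblastoma cell line. The libraries formed 2 groups of 3, control cells and cells that stably overexpress the long noncoding RNA XLOC013218, and each library was assigned to its group from its title. The series' design text describes the replicates as independent biological ones, and nothing in the labels says whether they were separate cultures, separate clones or cells of one selected population. The p-values therefore measure the spread between these 6 libraries, whatever its source. What the control cells carry, such as an empty vector, is not given in the sources used here.

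Per the labels' protocols, RNA was extracted with a phenol-based reagent, treated with DNase and made into stranded libraries after poly(A) selection. The series' design text instead describes libraries of cytoplasmic RNA made without such selection. The tables list no mitochondrially encoded RNA, no other RNA of the fixed list without a poly(A) tail and no nuclear-retained RNA of the fixed list. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, do bear on it: 24 of 56 were listed and 13 tested, with a median of 2.38 FPKM in control cells, against 57.1 FPKM for the cell cycle genes. Their low levels are what poly(A) selection would give, but H2BC12 averaged 80.8 FPKM and no library of known preparation was compared, so the contradiction was left open. The submitters' processing notes name TopHat, Bowtie, Cufflinks 2.2.1, RSEM 1.3.1, edgeR and the build hg18 without saying which step each served. Which of these tools gave the deposited values is not given in the sources used here.

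The authors deposited 1 table per library with gene-level FPKM values, that is, fragment counts scaled by transcript length and by the mapped fragments of the library, rounded to 2 decimals. Each table listed the same 20330 Ensembl gene identifiers, followed by assembled loci with XLOC numbers. The number of XLOC loci differed between libraries, at 462, 530 and 120 in control replicates 1 to 3 and 68, 591 and 318 in overexpression replicates 1 to 3, because the tables as used here end at different places in that part. In 5 of the 6 tables the last line was incomplete, and it was not read. The Ensembl genes were complete in every library. Symbols were taken from a table of gene names, which matched 19447 of the 20330 identifiers, and chromosomes and gene types from the GENCODE 29 annotation of GRCh38. Since the notes name another build, no coordinates are printed.

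FPKM values carry no read totals, so the depth in reads is unknown. The steps between low FPKM values of 1225 genes were used to estimate the relative depth of the libraries, taking control replicate 2 as 1.0. The estimates were 0.88 for control replicate 1, 0.77 for control replicate 3, and 0.77, 0.86 and 0.88 for overexpression replicates 1 to 3. On simulated data the method erred by at most 0.1 on the log2 scale. FPKM summed over the Ensembl genes to between 598683 and 621922 per library, and the share of these genes listed at 0 was between 22.6% and 23.3% in the control libraries and between 21.5% and 21.9% in the overexpression libraries, without overlap. No pair of libraries was a duplicate: between 0.222% and 0.367% of values were identical in a pair, and the SD of the log2 difference over tested genes was between 0.182 and 0.234 within groups and between 0.228 and 0.250 between groups.

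The tests were run on log2(FPKM + 1), with the values as deposited and no further scaling. Genes listed in all 6 tables with a mean of at least 1 FPKM over the 6 libraries were tested, 11731 in all. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low levels. The groups were compared with limma 3.58.1 in R 4.3.3, using limma-trend with the group as the only term, a two-sided test and Benjamini-Hochberg adjustment over all tested genes. An adjusted p under 0.05 was taken as the threshold. An exact permutation test of 3 libraries against 3 cannot give a p under 0.1, so single-gene calls rest on limma. Summaries of single genes and lists were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

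The grouping, the tests, 42 gene lists, the rule for naming genes and the alternative settings were fixed before the data were examined. The rule names the 12 genes with the largest increase and the 12 with the largest decrease among those past the threshold. Their groups must not overlap, the higher group must average at least 2 FPKM, and the gene must have a symbol. It also names up to 4 members per list with the lowest adjusted p among those past the threshold, and a set of study genes taken from the pathway the study is known for, with reference genes. Some of the genes and lists fixed in this way are not reported here. Any other gene named in the text was chosen after its values were seen. Lists with at least 5 tested members, 33 of the 42, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists. Camera with an estimated correlation and fry were run beside it, and members were also counted after adjustment over each list alone. That adjustment makes no correction across lists and corrects little in a short list. Of all 11731 tested genes, 1491 had an unadjusted limma p under 0.05, so single members that pass only in this way are weak calls. The genes of each of 23 chromosomes were tested as sets in the same way.

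The gene test was tested on simulated data made from the real libraries, with 11720 genes tested. At a true log2 fold change of 0.4 it recovered 52% of the changed genes, at 0.6 it recovered 76%, at 1 it recovered 100% and at 1.5 it recovered 98%. Of 164 calls in the simulation, 3 were false. Its errors were drawn independently for each gene, with no effect shared within a library, from the spread that limma had estimated. The real libraries need not meet these conditions, so the shares do not measure how reliable the real calls are.

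No locus with the number of XLOC013218 was found in the tables of control replicates 1 and 2 and overexpression replicate 2, and the tables of the other 3 libraries end before that number. The level of XLOC013218 was therefore not analysed here and the labels have no such check. Alternatives covered the pseudocount, the filter on low values, 3 other scalings, limma without a trend, with robust empirical Bayes or with array quality weights, the replicate number as a block, loci missing from a table taken as 0, and each library left out in turn. Tests for counts, an alternative for the case that the tables held counts, were not run.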

Results

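The transcriptome of U251 glioblastoma cells that stably overexpress the long noncoding RNA XLOC013218 was compared with that of control U251 cells, with 3 libraries per group. Gene levels were given as FPKM for 20330 Ensembl genes, of which between 11668 and 11748 per library reached 1 FPKM. The 20 most abundant genes took between 9.53% and 9.94% of the summed FPKM in each library. Depth in reads is unknown, and the estimated relative depth lay between 0.77 and 1.0 with overlap between the groups. The first principal component held 30.5% of the variance and placed the 3 control libraries on one side and the 3 overexpression libraries on the other. The level of XLOC013218 itself was not analysed here.

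The comparison asked which genes differ when XLOC013218 is overexpressed. Many of the genes that rose furthest belonged to the interferon response and to antigen presentation. RSAD2, which encodes the antiviral enzyme viperin, rose from 12.6 ± 0.492 to 35.8 ± 10.6 FPKM (SD, n = 3 per group), and HLA-B, a class I antigen-presenting molecule, rose from 156 ± 7.14 to 404 ± 93.7 FPKM. TGFBI, an extracellular matrix protein induced by TGF-beta, rose from 27.7 ± 1.57 to 53.9 ± 0.7499 FPKM. CLU, a secreted chaperone that astrocytes express, fell from 250.7 ± 23.15 to 166 ± 3.50 FPKM, and MSLN, a cell-surface glycoprotein, fell from 7.41 ± 0.307 to 3.75 ± 0.633 FPKM.

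Of 11731 genes tested, 61 passed an adjusted p of 0.05 in limma, 37 higher and 24 lower in overexpressing cells. After rescaling to TPM the same number passed, 50 of them shared, but as 30 higher and 31 lower. Most changes were small: 51 of the 61 were under 2-fold on the log2(FPKM + 1) scale, and 10 were over 2-fold, 7 higher and 3 lower. In all 61, the 3 overexpression values lay outside the range of the 3 control values, which held for 18.9% of all tested genes against 10% by chance. At an unadjusted p under 0.05 there were 1491 genes, where 587 would be expected by chance. Leaving out control replicate 1, 2 or 3 gave 1, 1 and 2 genes, all among the 61. Leaving out overexpression replicate 1 or 3 gave 14 and 23, with 10 and 22 of them among the 61. Without overexpression replicate 2 there were 60, 43 of them among the 61, with 48 higher and 12 lower. TGFBI passed in each of these 6 fits, whereas 12 of the 61, with NT5E and NLRP1 among them, passed in none. TGFBI was the only gene to pass with no filter on low values, without a trend in limma, or with missing loci taken as 0, while array quality weights gave 197 genes.

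**Figure D1:**
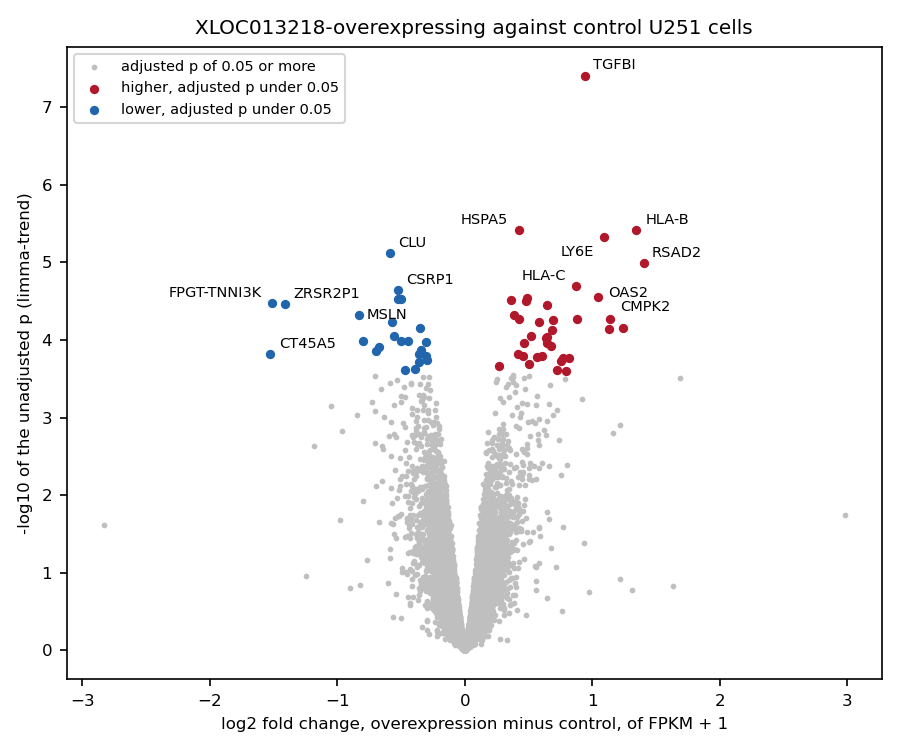
Each point is 1 of the 11731 tested genes, with its log2 fold change of FPKM + 1 (overexpression minus control) on the x axis and -log10 of its unadjusted limma p on the y axis. The 37 genes higher and 24 genes lower at an adjusted p under 0.05 are coloured, and TGFBI lies highest.

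Interferon-stimulated genes formed the largest group of called genes. Of 41 tested members of the list, 15 rose, 0 fell and 26 did not pass over all genes, while 37 were higher when adjusted over the list alone. The number that rose was 11 after rescaling to TPM, 8 under quantile normalization, 9 with the replicate number as a block, 21 with array quality weights and 0 with no filter on low values, without a trend in limma or with missing loci taken as 0. RSAD2 (ENSG00000134321, chromosome 2) had a log2 fold change of 1.40 (SE 0.16, limma adjusted p = 0.0202). OAS2 (ENSG00000111335, chromosome 12), which makes the 2-5A messenger that activates RNase L, rose from 53.6 ± 4.95 to 113 ± 26.0 FPKM with a log2 fold change of 1.05 (SE 0.14, limma adjusted p = 0.0242). CMPK2 and MX2, the latter an antiviral GTPase, rose by log2 fold changes of 1.14 and 1.13 (limma adjusted p = 0.0277 and 0.0302). OAS1 rose from 133 ± 3.26 to 209 ± 29.97 FPKM, TRIM22 from 24.3 ± 2.08 to 46.0 ± 9.26 FPKM, and OASL from 15.5 ± 1.62 to 28.0 ± 6.32 FPKM. The remaining risen members were IFI6, ISG15, MX1, IFIT1, IFI27, USP18, OAS3 and IFITM1, with log2 fold changes between 0.52 and 0.72. XAF1, at 2.26 ± 0.879 FPKM in control and 9.92 ± 4.63 FPKM in overexpressing cells, had the largest log2 fold change of the list, 1.68, and did not pass (limma adjusted p = 0.0515). IRF9, a transcription factor of the pathway, was at 72.8 ± 1.64 and 74.2 ± 6.38 FPKM and did not pass. LY6E (ENSG00000160932, chromosome 8), an interferon-induced surface protein outside the list, rose from 227 ± 16.9 to 490 ± 89.5 FPKM with a log2 fold change of 1.09 (SE 0.12, limma adjusted p = 0.0139).

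Some antigen presentation genes rose too. Of 13 tested members, 6 rose, 0 fell and 7 did not pass over all genes, and 11 were higher when adjusted over the list alone. HLA-B (ENSG00000234745, chromosome 6) had a log2 fold change of 1.34 (SE 0.14, limma adjusted p = 0.0139) and HLA-C rose from 280 ± 17.5 to 518 ± 87.4 FPKM (log2 fold change 0.87, limma adjusted p = 0.0242). TAP1, a subunit of the peptide transporter, rose from 46.7 ± 2.33 to 76.2 ± 12.4 FPKM, and the immunoproteasome subunits PSMB9 and PSMB8 rose by log2 fold changes of 0.77 and 0.46. NLRC5, the transactivator of class I genes, rose from 13.5 ± 0.139 to 19.6 ± 2.16 FPKM. B2M, the light chain of class I molecules, was at 2097 ± 94.99 and 2900 ± 348.5 FPKM and missed the threshold at a limma adjusted p of 0.0515. Class I HLA genes are near-identical in part, so the split of reads among them is uncertain.

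The interferon list had a median log2 fold change of 0.55 and the antigen presentation list one of 0.50. Both were higher by camera at the preset correlation (limma adjusted p = 4.92e-36 and 3.05e-16), but neither call held when the correlation was estimated, with limma adjusted p = 0.2997 for both with an estimated correlation. The estimated correlation between members was 0.77 and 0.83, against the preset 0.01. By fry in limma the adjusted p was 0.0828 and 0.0706. The mean deviation of the interferon genes from the control mean was 0.50, 0.35 and 0.82 in overexpression replicates 1 to 3, and in the 3 control libraries it lay between -0.08 and 0.04. The number of risen interferon genes was 8 without overexpression replicate 3, 1 without overexpression replicate 1, 17 without overexpression replicate 2 and 0 without any 1 of the control replicates, while their median log2 fold change stayed between 0.41 and 0.66 in these fits. An exact permutation test of the list means gave p = 0.1 for both lists, the smallest that 3 libraries against 3 allow.

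Outside these lists, 16 genes rose. TGFBI (ENSG00000120708, chromosome 5) had the lowest p of all genes, with a log2 fold change of 0.94 (SE 0.06, limma adjusted p = 0.000461), and lay between 26.6 and 29.5 FPKM in control and between 53.2 and 54.7 FPKM in overexpressing cells. NT5E, the ectoenzyme CD73 that forms adenosine, rose from 5.34 ± 1.02 to 10.1 ± 1.36 FPKM (log2 fold change 0.81, limma adjusted p = 0.0384). CXCL8, a chemokine for neutrophils, rose from 9.91 ± 0.547 to 16.1 ± 2.11 FPKM and was the only member of the 16 tested NF-kB and inflammatory genes to pass, over all genes and when adjusted over the list alone. THBS1, a matrix glycoprotein that activates TGF-beta, rose from 98.3 ± 6.34 to 138 ± 8.91 FPKM. FOSL1, an AP-1 transcription factor, rose from 34.8 ± 0.366 to 47.0 ± 3.15 FPKM, and HSPA5, the main chaperone of the endoplasmic reticulum, from 196 ± 4.41 to 264 ± 7.33 FPKM (log2 fold change 0.42, SE 0.04, limma adjusted p = 0.0139). The gene ENSG00000226907, which has no symbol in the table of names, rose from 1.60 ± 0.615 to 5.09 ± 0.972 FPKM, with a log2 fold change of 1.24, the third largest increase among called genes.

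Among the genes that fell, those with the largest log2 changes were at low levels. CT45A5 (2.60 ± 0.297 FPKM in control), FPGT-TNNI3K (2.58 ± 0.906 FPKM) and ZRSR2P1 (2.06 ± 0.329 FPKM) had log2 fold changes of -1.52, -1.51 and -1.41 (limma adjusted p = 0.0384, 0.0242 and 0.0242). CT45A5 belongs to a multicopy cancer-testis family, FPGT-TNNI3K is a readthrough of a pair of neighbouring genes and ZRSR2P1 is a processed pseudogene, so their values depend on how shared reads were split and are uncertain. The parent genes FPGT (8.65 ± 1.14 and 9.75 ± 1.15 FPKM) and ZRSR2 (5.28 ± 0.633 and 5.43 ± 0.537 FPKM) differed by less than the spread between libraries. MSLN (ENSG00000102854, chromosome 16) had a log2 fold change of -0.83 (SE 0.12, limma adjusted p = 0.0277). FNDC4 fell from 14.4 ± 1.81 to 7.84 ± 1.26 FPKM, FAIM2, an inhibitor of Fas-mediated cell death in neurons, from 9.05 ± 0.207 to 5.23 ± 0.848 FPKM, and HAS2, a hyaluronan synthase, from 6.27 ± 0.210 to 3.58 ± 0.477 FPKM. CLU (ENSG00000120885, chromosome 8) had a log2 fold change of -0.58 (SE 0.07, limma adjusted p = 0.0179). RGMA, an axon guidance protein, fell from 32.1 ± 2.27 to 21.4 ± 2.00 FPKM, NLRP1, an inflammasome sensor, from 15.3 ± 1.15 to 10.1 ± 0.684 FPKM, PRSS12, a secreted serine protease, from 19.9 ± 0.575 to 13.6 ± 0.738 FPKM, and CSRP1, a LIM-domain protein, from 234 ± 17.8 to 162 ± 10.6 FPKM.

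**Figure D2:**
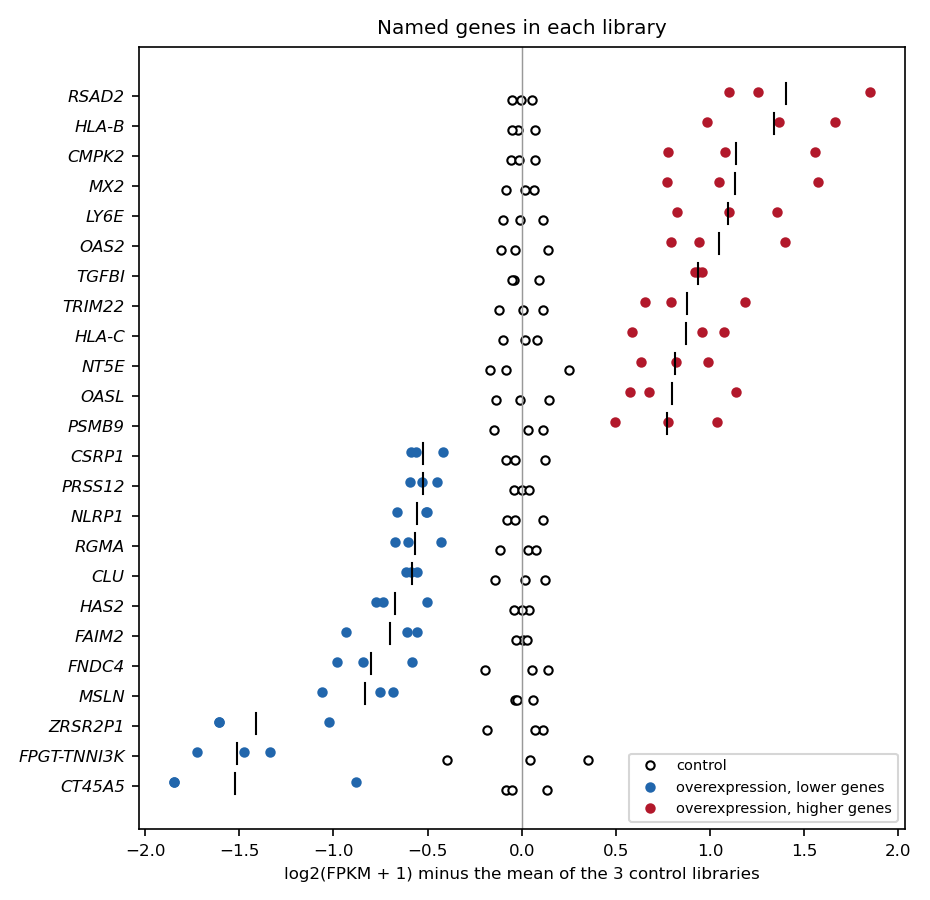
Each row shows 1 of the 24 genes that the naming rule took, 12 with the largest called increases and 12 with the largest called decreases among genes with a symbol, with log2(FPKM + 1) minus the control mean on the x axis for each of the 3 control libraries (open) and 3 overexpression libraries (filled), and a bar at the overexpression mean. The overexpression points of TGFBI and CLU lie close together, whereas those of RSAD2, HLA-B, CMPK2 and MX2 spread, with overexpression replicate 3 highest.

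Mesenchymal and extracellular matrix genes moved in both directions. Of 37 tested members, TGFBI and THBS1 rose, COL6A2, a chain of collagen VI, fell from 108 ± 4.44 to 83.8 ± 5.31 FPKM, and 34 did not pass. When adjusted over the list alone, 3 were higher and 5 lower. The median log2 fold change was -0.02, the mean was 0.04 and camera's direction was up, without a call (limma adjusted p = 0.991). The mixed form of fry in limma, which asks whether members changed in either direction, gave an adjusted p of 2.6e-05. Most of the 33 tested lists passed this form, so passing it does not set a list apart. VIM, an intermediate filament protein, was at 3840 ± 222 and 3581 ± 109 FPKM and did not pass.

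Genes of the unfolded protein and integrated stress response were higher as a list. Of 29 tested, HSPA5 alone rose over all genes and 28 did not pass, whereas 14 were higher when adjusted over the list alone, and the median log2 fold change was 0.18 (camera, limma adjusted p = 2.94e-14, and adjusted p = 0.0964 with an estimated correlation, so the call did not hold). DDIT3, the transcription factor CHOP, was at 30.3 ± 0.262 and 39.8 ± 3.58 FPKM, and CALR, a calcium-binding chaperone, at 791 ± 21.7 and 935 ± 11.5 FPKM, both at a limma adjusted p of 0.0537. MYC target genes (31 tested, 0 called over all genes, 9 higher when adjusted over the list alone) had a median of 0.13, heat shock genes (15 tested, 0 called, 1 higher when adjusted over the list alone) a median of 0.13, and genes of the TGF-beta pathway (24 tested, 0 called, 2 higher when adjusted over the list alone) a median of 0.15. MYC itself was at 31.9 ± 1.38 and 40.1 ± 4.47 FPKM, HSPA1B at 142 ± 1.43 and 163 ± 7.06 FPKM, and PMEPA1, a TGF-beta target, at 14.8 ± 1.28 and 20.3 ± 2.08 FPKM, none past the threshold. Camera at the preset correlation gave limma adjusted p = 1.22e-09, 1.39e-05 and 6.89e-05 for the MYC, heat shock and TGF-beta lists. With an estimated correlation none of these calls held, with limma adjusted p = 0.0964 with an estimated correlation for the heat shock and TGF-beta lists and adjusted p = 0.149 with an estimated correlation for the MYC list. The estimated correlation was 0.0815 for the stress response list, 0.0861 for MYC, 0.0087 for heat shock and -0.0201 for TGF-beta. The last 2 lie below the preset 0.01, so a higher correlation between members was not what ended those 2 calls. By fry, which tests the members alone, all 4 lists passed in limma (adjusted p = 0.0177, 0.0245, 0.0348 and 0.0171 for the stress response, MYC, heat shock and TGF-beta lists).

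Cell cycle, immediate early and ribosomal protein genes differed little. The 45 tested cell cycle genes had 0 calls over all genes, 0 when adjusted over the list alone and a median log2 fold change of 0.09 (camera, limma adjusted p = 1.86e-05, and adjusted p = 0.519 with an estimated correlation). Their mean in overexpression replicate 1, at 0.0102, lay within the control libraries. The difference of 0.08 went to 0.05 without overexpression replicate 2, and lay between 0.07 and 0.11 with any other library left out. FOXM1, a mitotic transcription factor, was at 90.1 ± 2.54 and 102 ± 3.80 FPKM and MKI67, a proliferation marker, at 48.7 ± 4.001 and 50.4 ± 3.36 FPKM, neither past the threshold. Of 25 tested immediate early genes, FOSL1 rose and 24 did not pass, 3 were higher when adjusted over the list alone, and the median was 0.07 (camera, limma adjusted p = 0.0120, and adjusted p = 0.332 with an estimated correlation). This last call was lost without control replicate 3 (adjusted p = 0.0572 in limma), without overexpression replicate 1 (adjusted p = 0.0996) and with array quality weights (adjusted p = 0.0560 in limma), while over all its alternatives the adjusted p ran from 0.00102 to 0.332 in limma. The 77 cytosolic ribosomal protein genes had 0 calls either over all genes or adjusted over the list alone and a median of 0.03 (camera, limma adjusted p = 0.0178, and adjusted p = 0.858 with an estimated correlation). Their mean turned from 0.03 to -0.01 under quantile normalization, to -0.003 without control replicate 3 and to -0.02 without overexpression replicate 2, and lay between 0.05 and 0.07 without control replicate 1, overexpression replicate 1 or overexpression replicate 3. The call was also lost with no filter on low values, without a trend in limma and with array quality weights (limma adjusted p = 0.0903, 0.0574 and 0.214).

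**Figure D3:**
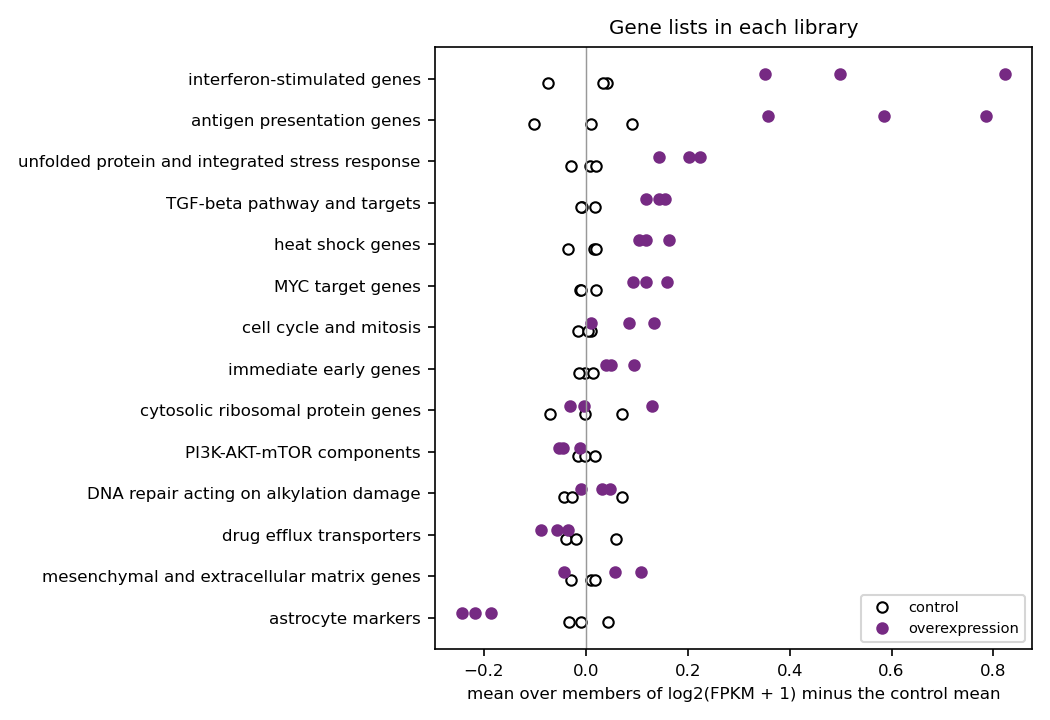
For 14 gene lists, the mean over tested members of log2(FPKM + 1) minus the control mean is plotted on the x axis for each of the 3 control libraries (open) and the 3 overexpression libraries (filled). The interferon-stimulated genes lie at 0.35, 0.50 and 0.82 in the overexpression libraries, and the PI3K-AKT-mTOR components near 0 in both groups.

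The genes of the pathway the study is known for did not pass the test. PIK3R2 (ENSG00000105647, chromosome 19), a regulatory subunit of PI3K, was at 92.3 ± 3.89 FPKM in control and 80.4 ± 1.78 FPKM in overexpressing cells, with a log2 fold change of -0.20 (SE 0.05, limma adjusted p = 0.140). Its overexpression values all lay below its control values, as did those of AKT1, PIK3CA and EGFR, and it passed only with array quality weights (limma adjusted p = 0.0467, in a range up to 0.411 over its alternatives). PIK3R1 was at 12.2 ± 1.82 and 13.2 ± 0.240 FPKM, PIK3CA at 16.97 ± 0.477 and 14.9 ± 0.891 FPKM, and AKT1 at 127 ± 4.69 and 116 ± 2.70 FPKM, with limma adjusted p = 0.672, 0.339 and 0.295. The transcription factor SP1 was at 20.1 ± 0.665 and 19.8 ± 1.29 FPKM. EGFR (27.1 ± 0.368 and 24.0 ± 1.15 FPKM), CCND1 (81.6 ± 3.01 and 85.2 ± 5.28 FPKM) and BCL2 (2.33 ± 0.725 and 1.78 ± 0.346 FPKM) did not pass. The reference genes GAPDH and ACTB were at 3468 ± 170 and 3550 ± 181 FPKM and at 2773 ± 142 and 2720 ± 70.4 FPKM. MGMT, the enzyme that removes alkyl groups from guanine, was listed at 0 in all 6 libraries. The 29 tested PI3K-AKT-mTOR components had 0 calls over all genes, 0 when adjusted over the list alone and a median log2 fold change of -0.03 (camera, limma adjusted p = 0.387). By fry in limma the adjusted p was 0.147 for a shared direction and 0.000881 in the mixed form. Most of the tested lists passed the mixed form, so this value does not set the PI3K-AKT-mTOR list apart.

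Lists related to drug response and cell death were not called by camera. DNA repair genes acting on alkylation damage (26 tested) had a median log2 fold change of 0.03 (limma adjusted p = 0.713) and drug efflux transporters (8 tested) one of -0.07 (limma adjusted p = 0.253). Among the transporters, ABCC1 was at 41.7 ± 1.32 and 33.9 ± 0.869 FPKM, which missed the threshold over all genes (limma adjusted p = 0.0537) and was the 1 lower gene when adjusted over the list alone. The medians were -0.02 for anti-apoptotic genes (9 tested, limma adjusted p = 0.668) and -0.04 for pro-apoptotic genes (18 tested, 0.991). None of these lists had a call over all genes, and apart from ABCC1 none had one when adjusted over the list alone. The mixed form of fry in limma gave an adjusted p of 0.00102 for the drug efflux transporters and between 0.180 and 0.596 for the other lists of this paragraph. Since most tested lists passed this form, it does not set the transporters apart.

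The remaining pathway lists were not called by camera either. Most of them passed the mixed form of fry, as most tested lists did, for example hypoxia and glycolysis genes (limma adjusted p = 0.000229). Receptor tyrosine kinases and ligands (26 tested) had 0 calls over all genes and 1 lower gene when adjusted over the list alone, ERBB2, at 32.9 ± 3.02 and 25.2 ± 1.80 FPKM, with a median of -0.05 (camera, limma adjusted p = 0.536). Of 29 autophagy and lysosome genes, MAP1LC3A, an LC3 protein of autophagosomes, fell from 43.0 ± 2.42 to 31.3 ± 2.17 FPKM and was the only call over all genes and when adjusted over the list alone (median -0.03, camera, limma adjusted p = 0.244). In the Wnt list (23 tested, median -0.04, limma adjusted p = 0.991) DKK1, a secreted Wnt antagonist, was at 189 ± 7.92 and 237 ± 16.7 FPKM and was the 1 higher gene when adjusted over the list alone. In the Notch list (15 tested, median 0.05, limma adjusted p = 0.5998) HES4 and JAG1 were the 2 higher genes when adjusted over the list alone, at 52.1 ± 5.51 and 73.7 ± 12.7 FPKM and at 17.5 ± 0.841 and 23.3 ± 3.61 FPKM. NRF2 target genes (19 tested, median -0.02, limma adjusted p = 0.766) had TKT as the 1 lower gene when adjusted over the list alone, and fatty acid synthesis genes (13 tested, median -0.04, limma adjusted p = 0.5998) had FADS2. Glioma stem cell genes (14 tested, median 0.00, limma adjusted p = 0.668) had MYC and ID1 higher and SOX2 lower when adjusted over the list alone, and epithelial junction genes (9 tested, median -0.11, mean 0.01, camera direction up, limma adjusted p = 0.991) had DSP higher. For the NF-kB and inflammatory genes the median was 0.01 (limma adjusted p = 0.252). DNA replication (38 tested, median 0.00), hypoxia and glycolysis (32 tested, median -0.00), cholesterol synthesis (23 tested, median 0.04) and nuclear-encoded oxidative phosphorylation genes (74 tested, median -0.01) had 0 calls over all genes or adjusted over the list alone, with limma adjusted p between 0.252 and 0.821. Of the 56 replication-dependent histone genes 24 were listed and 13 tested, with 0 calls over all genes, 1 lower gene when adjusted over the list alone (H2AC13) and a median of 0.09 (camera, limma adjusted p = 0.252). Of 9 metallothioneins 3 were tested, with MT2A the 1 higher gene when adjusted over the list alone, a median of -0.03 and a mean of 0.02. Adjustment over 3 genes corrects little. The single members of this paragraph that passed only over their own list are weak calls, since no correction was made across lists.

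Markers of astrocytes lay lower as a list by fry only. Of 7 tested, CLU fell and 6 did not pass over all genes, and 2 were lower when adjusted over the list alone, the other being GFAP, the astrocytic intermediate filament protein, at 41.6 ± 6.06 and 21.6 ± 7.91 FPKM (limma adjusted p = 0.107). The list's adjusted p was 0.0245 by fry and 0.0564 by camera in limma, and adjusted p = 0.330 with an estimated correlation. Its median log2 fold change was -0.06 with 3 of 7 members above 0, against a mean of -0.22, so CLU and GFAP carried most of the fall. Neuron markers (6 tested, median 0.07, limma adjusted p = 0.668) and fibroblast markers (7 tested, median -0.17, limma adjusted p = 0.425) had 0 calls over all genes or adjusted over the list alone. Too few members for a set test reached the filter among oligodendrocyte (3), microglia and macrophage (2), endothelial (1), erythroid (0) and carcinoma-type epithelial markers (2). Of these only CD68, at 7.19 ± 0.4996 and 10.1 ± 0.847 FPKM, was higher when adjusted over the list alone, which corrects little over 2 genes. The 3 oligodendrocyte markers had a median of 0.03 and a mean of -0.02. No member of the lists of mitochondrially encoded genes, other RNAs without a poly(A) tail and nuclear-retained RNAs was listed in the tables.

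By chromosome, no set of genes was called by camera in limma among 23 tested, and 1 had an unadjusted p under 0.05. Chromosome 6, which carries the HLA genes, held 7 higher and 1 lower gene among 595 tested, and its set had the lowest p (limma adjusted p = 0.167, and adjusted p = 0.255 with an estimated correlation). The median log2 fold change of its genes was 0.03.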

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

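All tests in this part were chosen after the values had been seen. Of the assembled loci with XLOC numbers that the comparison left out, 462 had a value in at least 1 library of each group, and 5 of them lay at 1 FPKM or more in overexpressing cells and over 2-fold above the highest control library. XLOC_012974 was at 1.06 FPKM in overexpression replicate 2 and listed at 0 in control replicates 1 and 2. XLOC_015761, XLOC_016336 and XLOC_016337 were at 1.72, 3.39 and 3.31 FPKM in overexpression replicate 2 and at 0.59, 1.27 and 1.03 FPKM in control replicate 2. Each of these comparisons has 1 overexpression library and no replicate check.

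XLOC_010526 stood apart from the rest, at 272 FPKM in overexpression replicate 2, 0.2 FPKM in control replicate 1 and 0 in control replicate 2. It was not analysed in the other 3 libraries, whose tables end before it. Lone high values that arise in any library stay open: the other 5 libraries held 0 genes or loci at 100 FPKM or more with all other values under 1, but such values may be rare, and 3 of these tables list few XLOC loci. Its ratio of FPKM + 1 to the higher of both controls was 228 and ranked 1 among 20792 genes and loci, where the next was 15.2. Another candidate explanation is that this locus holds the overexpressed lncRNA under another number, which stays open too because no other overexpression library gives its value.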

How the results depend on the processing

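Leaving out the XLOC loci was added after the data were seen and gave the same 61 genes. The 61 called genes kept their direction under every setting that tested them. Since their groups did not overlap, only the 3 other scalings could have turned a direction. Without a filter on low values, without a trend in limma and with missing loci taken as 0, 1 gene passed each time (1 higher, 0 lower, 0 over 2-fold), with 17627 genes tested without the filter and 11919 with missing loci as 0; the cause was not tested. Array quality weights gave 197 genes (86 higher, 111 lower), all 61 among them; the cause was not tested. With 1 library left out, a smaller design, the calls ranged from 1 to 60, those higher from 1 to 48, those lower from 0 to 12 and those over 2-fold from 0 to 14. Replicates with the same number did not deviate together (correlations -0.0398, -0.0576 and 0.0446), so no strong shared effect was seen. With 3 libraries per group this cannot exclude that the numbers mark a shared batch, and no label says whether they do. With the replicate number as a block 19 genes passed (14 higher, 5 lower), 15 of them among the 61. Of the values of called lists, 166 kept direction and call, 20 lost the call and 3 turned sign. The number of called lists went from 9 to 0 with an estimated correlation and to 5 by fry for a shared direction, 4 of them among the 9. The values of single genes pool the named called genes with the study genes, which were uncalled in the main fit and could not lose a call. Of these values, 564 kept direction and side of the threshold, and this number includes uncalled genes that stayed uncalled. The 262 that lost the call all belong to called genes. A further 1 gained the call and 4 turned sign, all 4 near 0 and uncalled. Over the fits with 1 library left out, GAPDH ranged from -0.0079 to 0.0664 (-0.0039 without control replicate 3), SP1 from -0.0729 to 0.0075 and ACTB from -0.0676 to 0.0055. The mean of the ribosomal protein list was -0.0083 under quantile normalization and ranged from -0.0177 to 0.0677 with 1 library left out (-0.003 without control replicate 3); the cause was not tested. edgeR and DESeq2 were not run, since the tables hold FPKM, and XLOC013218 itself gave no value under any setting. With the depth in reads unknown, no counting error can be given for genes near 1 FPKM.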

Other observations

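The tests of explanations and of other splits in this part were chosen after the results had been seen, as were the genes named in the paragraphs on single genes, while the other scalings and the fits with a library left out were planned.

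Of the 61 called genes, 32 were in none of the fixed lists, and some of these are described here. SLC7A5, a transporter of large neutral amino acids, rose from 52.8 ± 2.27 to 74.2 ± 5.61 FPKM (SD, n = 3 per group), and MTHFD2, a mitochondrial enzyme of folate metabolism, from 72.9 ± 1.71 to 88.2 ± 2.00 FPKM. MICA, a stress-induced ligand of the NKG2D receptor, rose from 49.5 ± 0.978 to 63.8 ± 1.44 FPKM, and CDC42EP3, an effector of the GTPase CDC42, from 38.1 ± 1.60 to 50.1 ± 1.22 FPKM. KRT81, a hair keratin with close paralogs, and DHRS2, a short-chain dehydrogenase, rose by log2 fold changes of 0.75 and 0.69. CADM1, a cell adhesion molecule, fell from 66.3 ± 1.68 to 46.7 ± 4.04 FPKM, and CNR1, the cannabinoid receptor, from 31.7 ± 2.02 to 24.0 ± 1.03 FPKM. Of secreted proteins, FSTL1 fell from 287 ± 7.16 to 224 ± 12.8 FPKM and IGFBP2 from 290 ± 10.2 to 235 ± 10.6 FPKM. EEF1A2, PALM, SLC44A5, HOXB3, DHRS3 and TMEM54 also fell, with log2 fold changes between -0.50 and -0.30. Leaving out a control library ended the call of each of these genes.

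Some interferon-stimulated transcripts were already at high levels in the control cells, while others were not. Tested members of the list had a median of 52.3 FPKM in control cells, and RSAD2 averaged 12.6 FPKM there, at rank 6936 among all tested genes. IFI6 averaged 1911 ± 174 FPKM in control cells and ranked 20 among all tested genes there, with IFI27 (933 ± 69.9 FPKM) at rank 82 and ISG15 (839 ± 71.2 FPKM) at rank 98. In overexpressing cells they averaged 3077 ± 473, 1396 ± 149 and 1319 ± 193 FPKM.

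The higher interferon-stimulated and antigen presentation genes were set against 4 explanations. The median log2 fold change of the interferon list was 0.521 or more under 3 other scalings and 0.413 or more with each overexpression library left out, which argues against library scaling or 1 library as the whole cause. Of the leucocyte genes PTPRC, TYROBP, FCER1G and AIF1 the highest value in an overexpression library was 0.65 FPKM, far below what abundant transcripts of admixed immune cells would reach, although PTPRC was at 0.15 ± 0.02 and 0.52 ± 0.13 FPKM in the groups and CD68, which the control cells already express, at 7.19 ± 0.4996 and 10.1 ± 0.847 FPKM. IFNB1, which encodes interferon beta, was at 0.107 ± 0.0971 in control and 0.353 ± 0.119 FPKM in overexpressing cells (exact permutation p = 0.1, the smallest possible), so near the floor that interferon made by the cells stays open as a candidate cause. It was the only interferon gene looked at whose groups did not overlap. IFNA1 was at 0.0467 ± 0.0416 and 0.0667 ± 0.0651 FPKM, IFNE at 0.387 ± 0.126 and 0.357 ± 0.0710 FPKM and IFNL1 at 0.0267 ± 0.0462 and 0.0233 ± 0.0404 FPKM. IFNA2, IFNG, IFNL2 and IFNL3 were listed at 0 in every library. An effect of XLOC013218 itself, and one of how the stable line was made or selected, both stay open as untested hypotheses.

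The 9 lists called higher were compared with the differences that the other 9 splits of the 6 libraries give. Each of those splits mixes libraries of both groups and so keeps part of any real difference. For cell cycle genes another split gave 0.0771, against 0.0765 for the real one, and for ribosomal protein genes another gave 0.102, against 0.0317, so variation shared by the members may account for these calls. For the other 7 lists the real difference exceeded those of the other 9 splits, and 10 splits are too few to give a share under 0.05, so the same explanation stays open there. Among these 7, the estimated correlation between members ran from -0.02 for the TGF-beta list to 0.83 for the antigen presentation list.

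The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes libraries of both groups. A real difference would widen the spread within its groups and so lower its count of changed genes. Part of a real difference would also remain in its list differences, so these splits do not show what libraries without a difference would give. In limma, the real split gave 61 changed genes (1491 at an unadjusted p under 0.05) against at most 0 in another, and 10 over 2-fold against at most 0, so 1 of the 10 splits reached each count. It called 9 gene lists, a count reached by 2 of the 10 splits, and every other split also called lists, between 2 and 9 each. It called 0 chromosome sets against at most 5, so all 10 splits reached that count. The split that called 5 chromosomes set control replicates 1 and 2 and overexpression replicate 1 against the others, by camera at the preset correlation, and what gave these calls was not tested.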
